A study of Shewanella oneidensis with 8 samples.

How the data were processed

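RNA from 8 cultures of Shewanella oneidensis MR-1 carrying a glk and galP plasmid was hybridised in 1 colour to 8 Agilent arrays of 1 slide, 4 from fumarate-respiring and 4 from fermentative cells. The labels' protocols give growth with 40 mM fumarate and a 3 h incubation with or without fumarate, and the series design text gives 4 biological replicates per condition. Groups and replicate numbers were taken from the sample titles.

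The deposited spot intensity of each array (background-subtracted processed signal) was made with Agilent Feature Extraction 11.5.1.1 and protocol GE1_1105_Oct12, per the file headers. The submitters' processing notes name Agilent Feature Extraction 8.1 and limma 3.36.2. Per the file headers the software applied a multiplicative detrending to 6 of the 8 arrays, all but fumarate-respiring replicate 1 and fermentative replicate 3. No genome build is given in the sources used here. The authors' series value table held intensity values on a linear scale. They equalled limma's normexp correction of the median spot and background signals without offset and without scaling between arrays, to within 4.55e-06 units. Scale, centring and direction of that table are therefore known. Its medians over gene probes were 201, 51.4, 86.5 and 63.0 for fumarate-respiring replicates 1 to 4 and 148, 156, 109 and 54.2 for fermentative replicates 1 to 4.

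Values were log2 of the processed signal minus each array's 75th percentile of it over the 13379 gene probes. Control spots were left out, and 17 spots marked as outliers by the scanner software (0 to 10 per array) were set missing. No gene probe was saturated. A probe entered where it was well above background on at least 3 of 4 arrays of at least 1 group, which left 12017 probes. A gene's value was the mean over its entering probes, 3 per gene in most cases. This gave 4519 genes, and 250 locus tags on the array were not tested. Of 1973 called genes with 2 or 3 probes, the probes disagreed in the sign of the change for 29, and for 0 of them were probes called in opposite directions. Among the genes named here that disagreement concerned purM only.

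Gene identifiers on the array are locus tags. Of 4769 tags, 4137 were found in the reference gene table (assembly ASM14616v2) and 1220 carried a symbol there. Since the array names no build, no coordinates are given, and the table served for names and for neighbouring genes. Genes without a symbol are given by locus tag, or by the name used in a gene list where the list named the tag.

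Fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, fermentative minus fumarate-respiring, no covariate, two-sided), with Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p below 0.05. A second count required an absolute log2 fold change of 1 or more. Errors of fold changes are moderated standard errors, and errors of group means are SDs over 4 arrays. A gene not well above background on any array of 1 group has only a bound. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the gene's own value and the lowest value among probes well above background. Bounds are given as "at least N-fold".

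Gene lists were written from general knowledge of the organism before the data were examined, as were the fit, the rule for named genes and the alternatives. Of 24 lists, 23 were matched and a prophage list was not used, since the gene table holds no product text. In these lists 365 members were matched and 84 list symbols found no tag, so several lists are incomplete. Shifts were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists. Counts adjusted over the list alone use Benjamini-Hochberg within the list. No list of other cell types was made because the samples were pure cultures. The genes named are the 10 largest rises and 10 largest falls among called genes that were well above background on at least 3 of 4 arrays of both groups and did not overlap between groups. To these come up to 4 called members per list with the largest change and no overlap, of which the text gives examples, and 14 genes fixed by name (fccA, cymA, pflB, ackA, pta, ldhA, adhE, hydA, hyaB, mtrC, omcA, crp, arcA and etrA). Up to 5 bounded genes each way were named separately.

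The fit was tested on simulated data. Normal values were drawn with each gene's mean and its moderated SD from the fit to the 8 real arrays. The simulated noise thus met the assumptions of the fit, which real noise may not. For the comparison of fermentative with fumarate-respiring cells over 4519 genes, 20 of 67 genes changed 1.5-fold were called, 54 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 8 false calls among 148. Of 23 simulated lists, the 1 lowered by 1 log2 unit was called and 0 others were. Simulated values were drawn independently for each gene, and only a small part of the genes was changed. List members were therefore uncorrelated, so the list result does not test the preset correlation of 0.01. In the data, estimated correlations ran from 0.005 for iron uptake to 0.68 for ATP synthase.

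The alternatives were quantile normalization, median scaling, normexp background (offset 50) with 75th-percentile or quantile scaling, and the authors' series values. Others were no filter on dim probes, only probes above background on all 8 arrays, outlier spots kept, the median of probes, the brightest probe, a replicate block, array weights, a trended robust prior and leaving out each array. Lists were also tested with an estimated correlation and with fry, and 2-fold changes with treat. Normexp used median in place of mean spot signals, the median being the spot signal in the files. The signal before multiplicative detrending, and leaving out both arrays numbered 4, were chosen after seeing the data.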

Results

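Transcript levels of Shewanella oneidensis MR-1, a bacterium that respires with many electron acceptors under anoxic conditions, were measured on 8 arrays of 1 slide. The strain carried a plasmid with glk and galP, which encode a glucokinase and a sugar transporter. All cultures were grown with 40 mM fumarate and then incubated for 3 h, either with fumarate as electron acceptor (fumarate-respiring, 4 biological replicates) or without it (fermentative, 4 biological replicates). The series concerns fermentative growth in defined media with added amino acid sources, and its array design addresses how the transcriptome differs between fermentation and fumarate respiration. The share of gene probes well above background ranged from 76.2% on fermentative replicate 4 to 94.8% on fermentative replicate 1. The 75th percentile of the signal, a measure of array brightness, was 538, 124, 231 and 174 on fumarate-respiring replicates 1 to 4 and 395, 430, 294 and 140 on fermentative replicates 1 to 4. With 4 arrays per condition, the number of arrays limits the precision of each value.

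Removal of fumarate was accompanied by a broad change of the transcriptome. Genes of formate dehydrogenase-N, with the adjacent selA and selB, and most measured genes of the TCA cycle, the main NADH dehydrogenases and the bc1 complex and cbb3 oxidase fell. Most measured genes of anaerobic terminal reductases, mixed-acid fermentation, hydrogenases, cytochrome c maturation and heat shock chaperones rose, while hypF and clpX of these lists fell. The calls of the lists for the TCA cycle, NADH dehydrogenases, oxidases and the groups that rose were lost with a correlation estimated from the data (adjusted p = 0.0961 to 0.287 with an estimated correlation), and formate dehydrogenases were not called as a list. Of 4519 genes tested, 2120 changed at an adjusted p below 0.05 (limma, two-sided, Benjamini-Hochberg), 1124 rising and 996 falling in fermentative cells. At least 2-fold changes were found for 796 genes, 474 risen and 322 fallen. The 4 values of each group did not overlap for 2003 genes, which is expected by chance for 2.86% of genes. Correlations of arrays across genes, which are not independent replicates, were 0.965 to 0.992 within groups and 0.869 to 0.898 between groups. Normexp background correction with an offset of 50, followed by 75th-percentile scaling, lowered the count of changed genes to 1266 (553 risen, 713 fallen) and that of 2-fold changes to 323. In that setting 43 of the 110 named genes had a log2 fold change smaller in size by more than 1.5 times. The authors' series values, which equal normexp without the offset and were scaled in the same way, gave 6 such genes and 619 changes of at least 2-fold. Most of this shrinkage therefore came with the offset, which all later values named normexp include. With normexp and quantile normalization 2265 genes changed (1098 risen, 1167 fallen), 326 of them at least 2-fold, and limma's treat against a 2-fold change called 294.

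The largest falls lay in a run of adjacent genes from SO_0101 to SO_0109. Within it, fdnG, the catalytic subunit of formate dehydrogenase-N, was 23.7-fold lower in fermentative cells (log2 fold change -4.57 ± 0.17, SE, n = 4 per group, limma adjusted p = 1.38e-08). Its partner subunits fdxH (SO_0102, fdnH in the list fixed for formate dehydrogenases) and fdnI (SO_0103, named from that list) were 46.2-fold and 50.6-fold lower, with log2 fold changes of -5.53 ± 0.16 and -5.66 ± 0.15. The run continued with fdhE (39.0-fold lower) and fdhD (13.8-fold lower), whose products help to form active formate dehydrogenase. It also held selA (SO_0105, log2 fold change -4.58 ± 0.33) and selB (SO_0106, 20.3-fold lower), which encode selenocysteine synthase and the selenocysteine-specific elongation factor. The genes yedE (SO_0108) and yedF (SO_0109) were 26.2-fold and 20.2-fold lower. For selA and selB the log2 fold changes were -2.56 and -2.73 with normexp and 75th-percentile scaling. Among array means, fdhE lay at 4.00 ± 0.18 (SD, n = 4) log2 units relative to the 75th percentile in fumarate-respiring cells and at -1.29 ± 0.11 in fermentative cells. The flanking gene SO_0100 fell as well, by 6.21-fold, and SO_0110 fell by 1.33-fold. The formate dehydrogenase list as a whole was not called: of its 9 measured members 3 fell, all in this run, 1 rose and 5 were not called (median log2 fold change -0.11, camera adjusted p = 0.0625). The riser was fdhA2 (SO_4513, name from the list) with a log2 fold change of 1.44, a gene outside the rule for named genes. Leaving out fumarate-respiring replicate 1 or fermentative replicate 2 brought the list's adjusted p to 0.0493 or 0.0341. Its median ranged from -0.29 to 0.10 over 23 processing alternatives, being above 0 with array weights and without both arrays numbered 4.

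**Figure D1:**
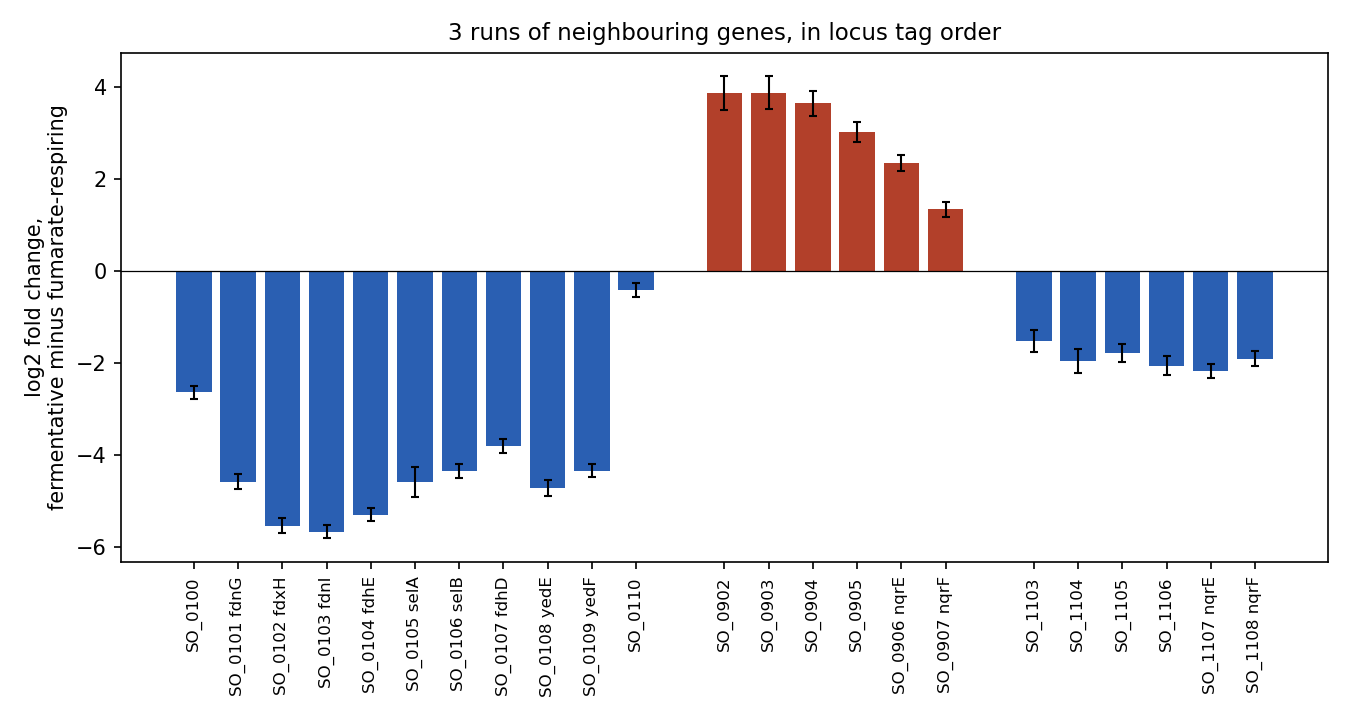
Log2 fold change of each gene (fermentative minus fumarate-respiring, bars, with the standard error, 4 arrays per group) in locus tag order for SO_0100 to SO_0110 and both runs that hold nqrE and nqrF. The SO_0101 to SO_0109 genes lie between -5.66 and -3.79, the SO_0902 to SO_0907 genes between 1.35 and 3.88, and the SO_1103 to SO_1108 genes between -2.17 and -1.51.

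Genes of anaerobic terminal reductases, fumarate reductase among them, rose. Of 17 measured members of the list, 14 rose and none fell at the adjusted threshold over all genes, and 15 rose when adjusted over the list alone. The median log2 fold change was 2.19, or 2.00 with the 3 members not well above background in fumarate-respiring cells set to their bounds (camera adjusted p = 5.63e-08, and adjusted p = 0.0961 with an estimated correlation). The median was 0.76 with normexp and 75th-percentile scaling. The periplasmic fumarate reductase gene fccA was 6.54-fold higher in fermentative cells (log2 fold change 2.71 ± 0.26, SE, n = 4 per group, limma adjusted p = 1.50e-05). Its electron donor cymA, an inner-membrane tetraheme cytochrome, was 6.05-fold higher (2.60 ± 0.27). The 3 adjacent genes listed as a polysulfide or thiosulfate reductase were not well above background on any fumarate-respiring array, so only bounds can be given. They were at least 8.47-fold higher for nrfD (SO_4060, psrC in the list), at least 4.01-fold higher for psrB (SO_4061, name from the list) and at least 2.66-fold higher for phsA (SO_4062, psrA in the list). These bounds hold for the processed signal only, since with normexp and 75th-percentile scaling the log2 fold changes of nrfD and psrB were 1.34 and 0.81. The members of the list that were not called were torA, ifcA and nrfA, with log2 fold changes of 0.54, 0.20 and 0.36, and these genes fall outside the rule for named genes. Outside the list, bounds of at least 4.17-fold and at least 2.89-fold were obtained for SO_4053 and SO_4404, and no called gene had such a bound in the falling direction. Probes well above background made up 92.2, 76.2, 81.9 and 81.7% on fumarate-respiring replicates 1 to 4. On fermentative replicates 1 to 4 they made up 94.8, 94.8, 89.2 and 76.2%, a difference that can favour bounds in the rising direction.

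Fermentation genes rose as a group. All 8 measured members of the list for pyruvate, acetate, lactate and ethanol metabolism rose, with the same count adjusted over the list alone (median log2 fold change 2.20, camera adjusted p = 2.29e-05, and adjusted p = 0.269 with an estimated correlation). The aldehyde and alcohol dehydrogenase gene adhE was 9.52-fold higher in fermentative cells (log2 fold change 3.25 ± 0.22, SE, n = 4 per group). Pyruvate formate-lyase pflB was 5.67-fold higher, the formate channel gene focA 4.69-fold, acetate kinase ackA 4.95-fold and the lactate dehydrogenase gene ldhA 3.30-fold. The log2 fold changes of adhE and ldhA were 1.52 and 0.75 with normexp and 75th-percentile scaling. The phosphate acetyltransferase gene pta rose by 0.68 ± 0.17 log2 units, a call that was lost when only the brightest probe per gene was used (adjusted p = 0.0501). The mean of the list was 0.66 on fermentative replicate 4, below the 0.97 to 1.01 of the other 3 fermentative arrays.

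Hydrogenase genes also rose: 11 of 13 measured members rose, 1 fell and 1 was not called, with the same counts adjusted over the list alone (median log2 fold change 1.51, camera adjusted p = 0.000500, and adjusted p = 0.269 with an estimated correlation). The [FeFe] hydrogenase gene hydA (SO_3920) was 4.72-fold higher in fermentative cells (2.24 ± 0.29), and the maturation gene hydG (SO_3923), close to it, 3.86-fold higher. The maturation gene hypD (SO_2091), which lies near the [NiFe] hydrogenase gene hyaB (SO_2098), was 6.75-fold higher. In fumarate-respiring cells hypD was well above background on 1 of 4 arrays and hydG on 2 of 4. With normexp and 75th-percentile scaling the log2 fold changes of hydA and hypD were 0.82 and 0.79 and the median of the list was 0.71. The [NiFe] hydrogenase gene hyaB was 1.91-fold higher (0.93 ± 0.21). With normexp and 75th-percentile scaling the calls of hydG and hyaB were lost (adjusted p = 0.289 and 0.310), and that of hyaB also with the brightest probe (adjusted p = 0.147) and with probes above background on all 8 arrays (adjusted p = 0.0945). Both calls were kept with normexp and quantile scaling (limma adjusted p = 0.000147 and 0.00173). The member that fell was hypF, with a log2 fold change of -0.75, and hydF was not called at -0.20. Both lie outside the rule for named genes.

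Cytochrome c maturation genes rose in all 5 measured cases, with the same count adjusted over the list alone (median log2 fold change 1.28, camera adjusted p = 0.00193, and adjusted p = 0.269 with an estimated correlation). The heme exporter genes ccmB and ccmA were 4.10-fold and 3.40-fold higher in fermentative cells, with log2 fold changes of 1.26 and 1.17 under normexp and 75th-percentile scaling. Of 8 genes for metal-reducing extracellular electron transfer, 6 rose and none fell, also adjusted over the list alone (median log2 fold change 0.58, camera adjusted p = 0.0415, and adjusted p = 0.269 with an estimated correlation). The outer-membrane cytochrome genes mtrC and omcA were 2.54-fold and 1.52-fold higher, and mtrA was 1.70-fold higher. The gene mtrE (SO_1781, name from the list) rose by 0.54 ± 0.15 but had a negative log2 fold change of -0.11 with normexp and 75th-percentile scaling. The list kept its call in 14 of 23 processing alternatives, with adjusted p from 0.0216 to 0.123. Without fermentative replicate 3 its adjusted p was 0.0606, and its median was 0.36 with normexp and 75th-percentile scaling and 0.29 with the brightest probe. The calls of omcA and mtrA were lost with the brightest probe per gene (adjusted p = 0.0724 and 0.268).

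The TCA cycle and glyoxylate shunt fell. Of 13 measured members 12 fell and none rose, with the same count adjusted over the list alone (median log2 fold change -1.55, camera adjusted p = 8.12e-08, and adjusted p = 0.0961 with an estimated correlation). The succinyl-CoA synthetase genes sucC and sucD were 6.97-fold and 4.43-fold lower in fermentative cells (sucC log2 fold change -2.80 ± 0.13, SE, n = 4 per group, limma adjusted p = 1.24e-07). The gene odhB (SO_1931, sucB in the list), of the 2-oxoglutarate dehydrogenase complex, was 4.41-fold lower, and the citrate synthase gene gltA (SO_1926, name from the list) 4.31-fold lower. The member that was not called was fumB, with a log2 fold change of -0.09, which lies outside the rule for named genes.

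NADH dehydrogenase genes fell in 13 of 16 measured cases, and 2 rose, with the same counts adjusted over the list alone (median log2 fold change -1.21, camera adjusted p = 6.33e-05, and adjusted p = 0.269 with an estimated correlation). The nuo genes of the proton-pumping complex fell together, among them nuoJ, which was 2.80-fold lower in fermentative cells. The sodium-pumping NADH:quinone oxidoreductase is encoded in 2 copies that moved apart. In the copy at SO_1103 to SO_1108, nqrE (SO_1107) was 4.51-fold lower and nqrF (SO_1108) 3.74-fold lower. In the copy at SO_0902 to SO_0907, nqrE (SO_0906) was 5.09-fold higher, nqrF (SO_0907) 2.54-fold higher and the adjacent SO_0903 14.7-fold higher. The directions of both runs were the same under all 6 scaling and background alternatives.

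The list of oxygen-linked oxidases and the bc1 complex also split. Of 9 measured members 7 fell and 2 rose, with the same counts adjusted over the list alone (median log2 fold change -1.61, camera adjusted p = 0.00554, and adjusted p = 0.269 with an estimated correlation). The bc1 complex genes petB (SO_0609) and petC (SO_0610) were 4.47-fold and 3.62-fold lower in fermentative cells, and ccoQ (SO_2362), of the cbb3 oxidase, was 3.78-fold lower. The bd oxidase gene cydA (SO_3286) was 3.85-fold higher. The names of these 4 genes come from the list.

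Chaperone and heat shock protease genes rose in 9 of 12 measured cases, 1 fell and 2 were not called, with the same counts adjusted over the list alone (median log2 fold change 1.51, camera adjusted p = 0.00152, and adjusted p = 0.287 with an estimated correlation). The disaggregase gene clpB was 7.77-fold higher in fermentative cells (log2 fold change 2.96 ± 0.20, SE, n = 4 per group). Of the DnaK system, dnaK was 4.92-fold, grpE 3.83-fold and dnaJ 3.77-fold higher. The member that fell was clpX, with a log2 fold change of -0.54, outside the rule for named genes.

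**Figure D2:**
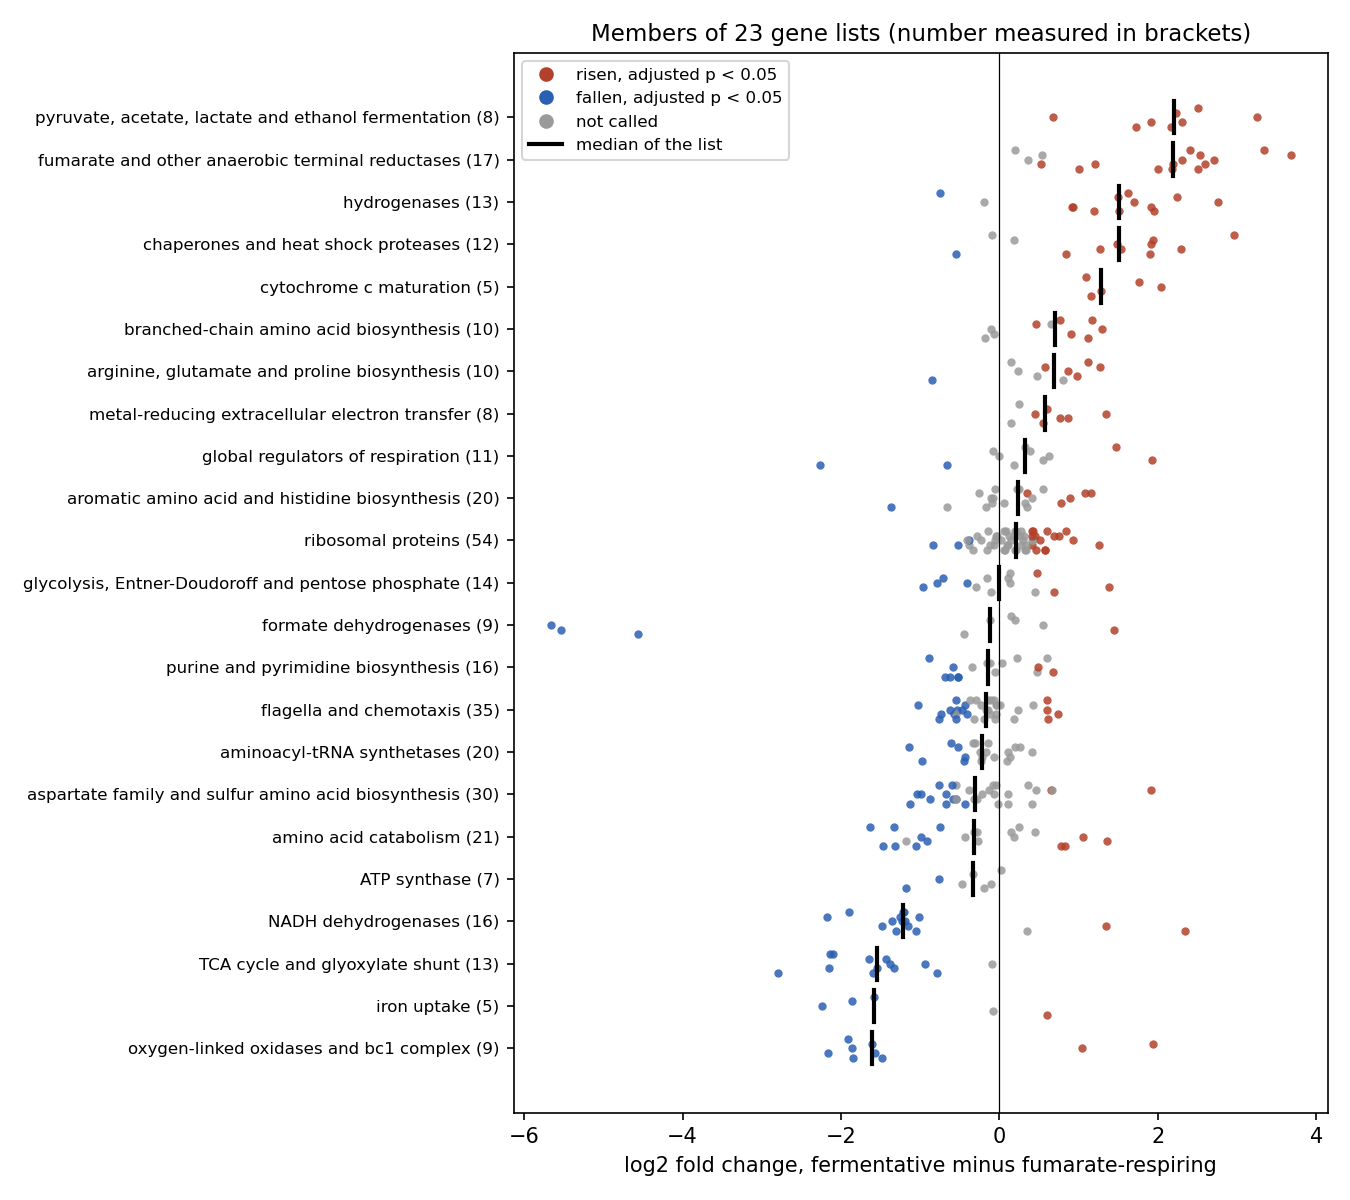
Log2 fold change (fermentative minus fumarate-respiring, horizontal axis) of each measured member of 23 gene lists, with the list median as a black bar and members coloured by their limma call. List medians run from -1.61 for oxygen-linked oxidases and the bc1 complex to 2.20 for the fermentation list, and the 3 formate dehydrogenase genes of the SO_0101 run lie below -4.5.

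Among called genes well above background on at least 3 arrays of both groups and without overlap, the 10 with the largest rises had no symbol in the reference annotation. SO_0844, which adjoins the periplasmic nitrate reductase gene napB (SO_0845), was 87.4-fold higher in fermentative cells (log2 fold change 6.45 ± 0.33, SE, n = 4 per group, limma adjusted p = 2.52e-07), measured with 1 probe. SO_1047 and SO_1048 were 21.2-fold and 19.5-fold higher. SO_1427, 2 tags away from the dimethyl sulfoxide reductase gene dmsA (SO_1429, name from the list), had a log2 fold change of 3.91 ± 0.23. SO_0902, SO_0903 and SO_0904 of the rising nqr run were 14.6-fold, 14.7-fold and 12.5-fold higher. SO_1532, SO_1911 and SO_0944 were 13.9-fold, 10.4-fold and 10.3-fold higher. With normexp and 75th-percentile scaling the log2 fold changes were 2.13 for SO_1427, 2.22, 2.41 and 2.40 for SO_0902, SO_0903 and SO_0904, 2.22 for SO_1911 and 1.71 for SO_0944. Among the 10 largest falls under the same conditions, SO_A0176 was the only gene outside the SO_0101 run, at 10.97-fold lower.

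Regulators of respiration were not called as a list: 2 of 11 members rose and 2 fell, also adjusted over the list alone (median log2 fold change 0.32, 0.01 to 0.38 over 23 processing alternatives, camera adjusted p = 0.428). The response regulator gene arcA was 2.78-fold higher in fermentative cells (1.47 ± 0.17, SE, n = 4 per group), and cpdA, a cyclic AMP phosphodiesterase gene, 3.79-fold higher. The adenylate cyclase gene cyaA (SO_4312, name from the list) was 4.81-fold lower (-2.27 ± 0.17, and -1.50 with normexp and 75th-percentile scaling), and arcS (SO_0577, name from the list) was 1.59-fold lower, a call lost with normexp and 75th-percentile scaling (adjusted p = 0.0685) and with the brightest probe (adjusted p = 0.166). With normexp and quantile scaling arcS kept its call (limma adjusted p = 0.00931). The cyclic AMP receptor protein gene crp had a log2 fold change of 0.55 ± 0.22 (limma adjusted p = 0.0616). It was called in 11 of 23 processing alternatives, with log2 fold changes from 0.42 to 0.87 over all 23. Among those that called it were the authors' series values (0.83, adjusted p = 0.00345), normexp with 75th-percentile scaling (0.80, adjusted p = 0.00849), array weights (0.72, adjusted p = 0.00232) and leaving out fermentative replicate 4 (0.76, adjusted p = 0.00386). The gene etrA had a log2 fold change of 0.32 ± 0.16 (limma adjusted p = 0.125), and without fumarate-respiring replicate 4 it was 0.43 with an adjusted p of 0.0364.

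**Figure D3:**
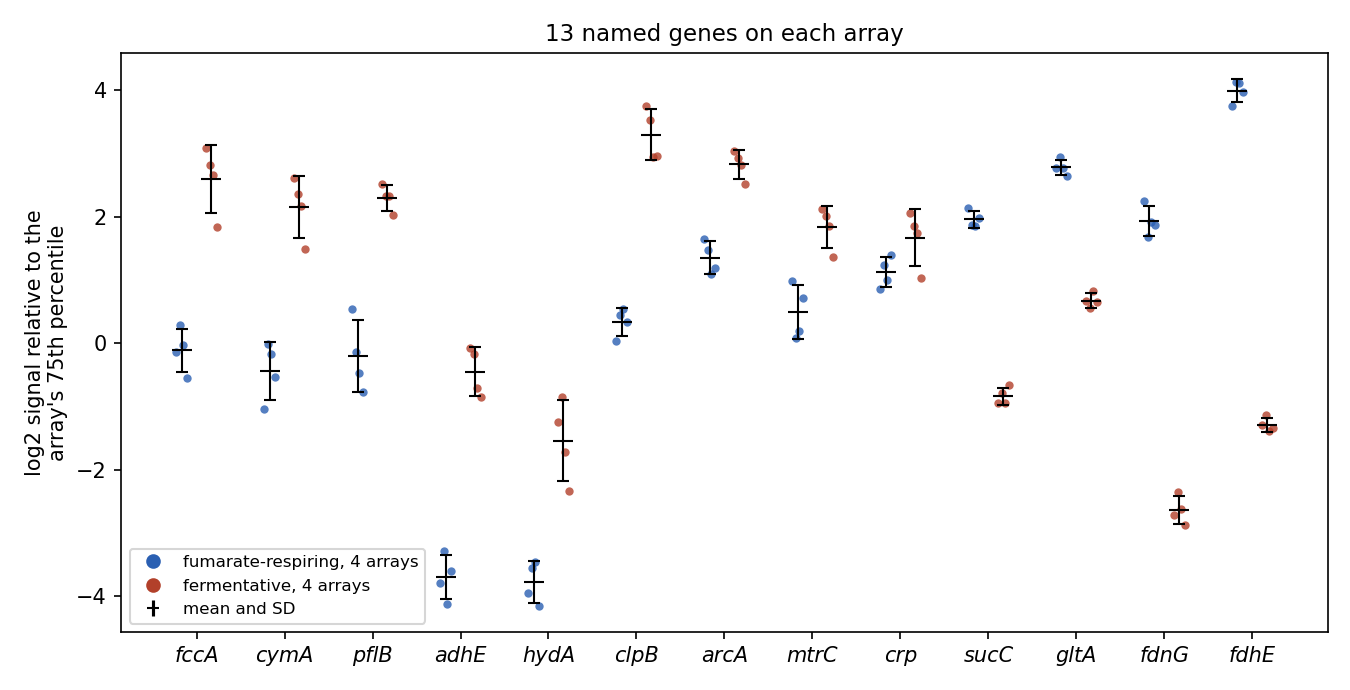
Log2 signal relative to the 75th percentile of each array for 13 named genes (points, 4 arrays per group, with mean and SD). The fermentative arrays lie above the fumarate-respiring ones for fccA, cymA, pflB, adhE, hydA, clpB, arcA and mtrC and below them for sucC, gltA, fdnG and fdhE, and the groups overlap for crp.

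Biosynthesis and catabolism of amino acids gave mixed results, and none of these lists was called. Of 10 arginine, glutamate and proline biosynthesis genes 5 rose and 1 fell (7 and 1 adjusted over the list alone, median log2 fold change 0.69, and 0.26 with normexp and 75th-percentile scaling, camera adjusted p = 0.0608), with glnA 2.18-fold and argA 2.41-fold higher in fermentative cells. Of 10 branched-chain amino acid genes 6 rose and none fell (7 adjusted over the list alone, median 0.71, and 0.19 with that scaling, camera adjusted p = 0.0608), with ilvA 2.18-fold (log2 fold change 0.52 with normexp and 75th-percentile scaling) and leuA 2.25-fold higher. With normexp and 75th-percentile scaling the calls of argA and leuA were lost (adjusted p = 0.354 and 0.488), and with the brightest probe that of glnA (adjusted p = 0.129). With normexp and quantile scaling argA and leuA kept their calls (limma adjusted p = 0.00378 and 0.0339). Of 20 aromatic amino acid and histidine genes 5 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.341), and the median was -0.10 with normexp and 75th-percentile scaling. Here hisG was 2.23-fold higher (adjusted p = 0.241 with that scaling) and tyrA 2.58-fold lower (log2 fold change -0.86 with that scaling). The call of hisG was kept with normexp and quantile scaling (limma adjusted p = 0.000474). Of 30 genes for the aspartate family and sulfur amino acids 2 rose and 11 fell, also adjusted over the list alone (median -0.30, camera adjusted p = 0.0643). The asparagine synthetase gene annotated asnB at SO_2767 was 3.78-fold higher, and dapD was 2.05-fold lower. The gene at SO_3175, which carries the same symbol, was 2.19-fold lower and is the first of 14 adjacent genes that fell, SO_3175 to SO_3188. Of 21 amino acid catabolism genes 4 rose and 8 fell, also adjusted over the list alone (median -0.32, camera adjusted p = 0.0893), with the arginine catabolism genes astD and astA 2.77-fold and 2.52-fold lower (astA -0.86 log2 units with normexp and 75th-percentile scaling), phhA 3.11-fold lower and gcvT 2.56-fold higher. With normexp and quantile scaling the log2 fold changes of astD, astA and phhA were -0.96, -0.74 and -1.04. Of 20 aminoacyl-tRNA synthetase genes none rose and 6 fell (3 adjusted over the list alone, median -0.23, camera adjusted p = 0.0839), with ileS 2.20-fold lower. Single arrays moved some of these lists across the threshold. Without fumarate-respiring replicate 3 the adjusted p was 0.0368 for arginine, glutamate and proline biosynthesis and 0.0345 for both the branched-chain and the aspartate family lists. For arginine, glutamate and proline biosynthesis it was 0.0486 without fumarate-respiring replicate 1, 0.0258 without fermentative replicate 1 and 0.0439 with the replicate block. Over the 23 alternatives the median ranged from -0.36 to -0.15 for the aspartate family, from -0.51 to -0.27 for amino acid catabolism and from -0.28 to -0.12 for aminoacyl-tRNA synthetases. The camera adjusted p was 0.0333 for aminoacyl-tRNA synthetases without fumarate-respiring replicate 4, and 0.0470 for amino acid catabolism with the brightest probe.

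The remaining lists were not called. Over 23 processing alternatives their medians ranged from 0.08 to 0.28 for ribosomal proteins, from -0.47 to -0.16 for ATP synthase, from -0.26 to -0.12 for flagella and chemotaxis, from -0.26 to -0.01 for purine and pyrimidine genes and from -0.12 to 0.23 for glycolysis and related genes. The range for iron uptake, measured in 22 of them, was -1.76 to -0.65. Of 54 ribosomal protein genes 15 rose and 3 fell (10 and 2 adjusted over the list alone, median log2 fold change 0.20, camera adjusted p = 0.0981), with rpmE 2.39-fold higher in fermentative cells (log2 fold change 1.25, and 0.81 without fumarate-respiring replicate 1). This list was called with normexp and 75th-percentile scaling (adjusted p = 4.11e-05), with the authors' series values (adjusted p = 0.0291) and without fermentative replicate 1 (adjusted p = 0.0154). Of 7 ATP synthase genes 2 fell and none rose, also adjusted over the list alone (median -0.33, camera adjusted p = 0.0839), with atpD 2.26-fold lower, and without fumarate-respiring replicate 3 the adjusted p was 0.0368. Of 5 iron uptake genes 3 fell and 1 rose, also adjusted over the list alone (median -1.58, camera adjusted p = 0.0608). Here alcA (SO_3030), hugA (SO_3669) and viuA (SO_4516), named from the list, were 4.74-fold, 3.63-fold and 2.99-fold lower (log2 fold changes of -0.86, -0.83 and -0.91 with normexp and 75th-percentile scaling), and feoB, which serves ferrous iron uptake, was 1.51-fold higher, a call lost with normexp and 75th-percentile scaling (adjusted p = 0.0611) and with the brightest probe (adjusted p = 0.0677). The call of feoB was kept with normexp and quantile scaling (limma adjusted p = 0.00852). In fermentative cells alcA was well above background on 2 of 4 arrays and hugA on 3 of 4. Without fumarate-respiring replicate 1 or 3 the adjusted p of the iron list was 0.0493 or 0.0428. Of 35 flagella and chemotaxis genes 4 rose and 11 fell, also adjusted over the list alone (median -0.17, camera adjusted p = 0.0608), with flgJ 2.04-fold lower (adjusted p = 0.0637 with normexp and 75th-percentile scaling), and the list's adjusted p was 0.0333 without fumarate-respiring replicate 4. The call of flgJ was kept with normexp and quantile scaling (limma adjusted p = 0.00145). Of 16 purine and pyrimidine genes 2 rose and 6 fell, also adjusted over the list alone (median -0.14, camera adjusted p = 0.304), with purL 1.85-fold lower. Of 14 glycolysis, Entner-Doudoroff and pentose phosphate genes 3 rose and 4 fell, also adjusted over the list alone (median -0.00, camera adjusted p = 0.709), with eda (SO_2486, name from the list) 1.95-fold lower and rpe 2.61-fold higher.

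In all, 9 of 23 lists were called with camera at its preset correlation. With a correlation estimated from the data camera called none of the 9 (0 of 23 at an adjusted p below 0.05, 3 of 23 at an unadjusted p below 0.05), and fry, which does not compare a list with other genes, called 17. Without fumarate-respiring replicate 3, 14 lists were called. Over 23 processing alternatives the 8 called lists other than extracellular electron transfer kept their direction and call, with adjusted p from 2.81e-08 to 0.0182. The fumarate-respiring and fermentative arrays occupied different rows of the slide, per the file headers, so slide row and group cannot be told apart.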

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

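The tests of background handling in the SO_0101 run and of array brightness, and the sorting of splits by how they mix the groups, were chosen after the results were seen. So was the signal without detrending. The SO_0101 run, the nqr runs and the rise of the anaerobic terminal reductase list were themselves picked for weighing from the results. In 270 groups of 4 arrays, 13 held an array far from the other 3, and chance alone marks about 1 in 20 groups. On fermentative replicate 4 the log2 signals relative to the 75th percentile were -1.52 for astD, 3.08 for SO_1048, -2.07 for hypE, -0.30 for ileS and 1.94 for atpA. On the same array the mean of the list for pyruvate, acetate, lactate and ethanol fermentation was 0.66, against 0.97 to 1.01 on the other 3 fermentative arrays. Fermentative replicate 1 stood apart for SO_1047 at 3.65, motY at 2.62 and ilvM at -2.59. Fumarate-respiring replicate 1 stood apart for yedE at 1.52 and for the mean of the NADH dehydrogenase list at 0.0440, against -0.24 to -0.19 on its 3 group mates. Fumarate-respiring replicate 3 stood apart for ilvD at -2.42 and fumarate-respiring replicate 4 for rpmF at 1.69.

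Of the 35 splits of the 8 arrays into 2 groups of 4, only the real split (1 of 35) gave 2120 changed genes in limma. The highest of the other splits was 0, with up to 570 genes at an unadjusted p below 0.05 against 2444 in the real split. The share of 1 in 35 lies below 0.05 but is the smallest these splits can give. In the other splits the group difference adds to the within-group spread and lowers their counts, so chance cannot be called excluded. The same holds for the 796 genes changed at least 2-fold, reached by 1 of 35 splits with 0 as the highest of the others. For the count of gene lists called with camera, 12 of 35 splits gave 9 or more and the highest of the others was 15, so this comparison does not exclude chance. The 11 other splits that reached 9 lists all kept 3 arrays of each group together and so carry part of the real contrast. The 18 splits that divided both groups evenly gave at most 5 lists.

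The fall of SO_0101 to SO_0109 was weighed first. Other probes within 3 rows and 3 columns of the run's probes on the array, 950 in number, had a median log2 fold change of -0.0283, which argues against a local defect of the arrays. The run's median, -4.58, came no nearer to 0 than -3.44 over the 6 scaling and background alternatives, which argues against background handling as the whole cause. Slide row coincides with group and stays open, and a response to the removal of fumarate is a hypothesis.

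The run SO_0902 to SO_0907 rose and the run SO_1103 to SO_1108 fell, and both hold nqrE and nqrF. Of the runs' 36 probes 0% went against the direction of their own run, but probes that bind both copies would draw the runs together, so this test decides nothing about runs that moved apart. Over the 6 scaling and background alternatives the smaller of both runs' absolute medians was 1.59, in the runs' own directions. Neither direction therefore depended on the choice among these alternatives. A shift of whole arrays moves both runs the same way, so this comparison could hardly have come out otherwise. How far shared binding narrowed the difference was not tested, slide row stays open, and a different use of the copies without fumarate is an untested hypothesis.

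The rise of the anaerobic terminal reductase list could reflect array brightness or the detrending applied to 6 of 8 arrays. With brightness as a covariate 98.3% ± 4.75 (SE, n = 4 per group) of the list's mean difference was left, and without the detrending 97.3% of its median was left, so both tables argue against these explanations. The median was 0.76 with normexp and 75th-percentile scaling (camera adjusted p = 1.50e-06) against 2.19. By the size limit used for named genes, 3 lists shrank in that setting, this list included. For the authors' series values, which lack only the offset, 0 lists did. Much of the drop therefore came with the offset, and a smaller effect of background handling on the size stays open. Slide row stays open here too, and a response of these genes to the removal of fumarate is a hypothesis.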

How the results depend on the processing

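The signal without multiplicative detrending and the omission of both arrays numbered 4 were chosen after seeing the data. The main counts were 2120 changed genes, 796 changed at least 2-fold and 9 called lists. With normexp and 75th-percentile scaling 1266 genes changed (553 risen), 1219 of them also called in the main setting, and 323 changed at least 2-fold (179 risen, 144 fallen). This setting moved the median log2 fold change of all genes from 0.04 to -0.10, and the cause was not tested. With normexp and quantile scaling 2265 genes changed (1098 risen, 1167 fallen) and 326 changed at least 2-fold (191 risen, 135 fallen). The authors' series values, which are normexp without the offset and had 75th-percentile scaling, gave 619 changes of at least 2-fold. Their difference from the 323 with the offset and the same scaling therefore came with the offset. For quantile scaling no setting of normexp without the offset was run. Treat, which requires more than a 2-fold change, called 294 (181 risen, 113 fallen). Camera with an estimated correlation called 0 lists and fry 17. Leaving out each array gave 1790 to 2103 changed genes, 773 to 829 2-fold changes and 8 to 14 lists, the 14 without fumarate-respiring replicate 3. Without the detrending 2206 genes changed and without both arrays numbered 4, 2124. No gene called in the main setting was called in the opposite direction in any of the 23 processing alternatives.

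Of 2513 values of named genes under alternatives, 2455 kept direction and side of the threshold, 43 lost the call, 12 gained it and 3 changed direction. These were mtrE (-0.11) and hisD (-0.0630) with normexp and 75th-percentile scaling and purM (-0.0900) with the brightest probe. Of 574 list values 524 kept direction and side, 18 lost the call, 27 gained it and 5 changed the test's direction. These were aromatic amino acid and histidine biosynthesis with normexp and 75th-percentile scaling (median -0.10), and glycolysis with that scaling (-0.0639), with normexp and quantile scaling (-0.0836), with the authors' series values (-0.0715) and without fumarate-respiring replicate 1 (0.11). The glycolysis median ranged from -0.12 to 0.11 on leaving out each array in turn. The cause was not tested. Signal over background limits dim genes, since as few as 76.2% of probes were well above it on an array.

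The labels number the replicates 1 to 4 in both groups, and the number is also the array's column on the slide. Same-numbered arrays deviated from their group means with correlations of 0.03 to 0.12 across genes, against -0.14 to 0.11 for other numbers, and 3 of 8 arrays correlated best with their own number. The second principal component, with 9.38% of the variance, nevertheless fell from number 1 to number 4 in both groups (8.28, 3.23, -2.21 and -7.83 for fumarate-respiring, 12.6, 7.57, 0.773 and -22.4 for fermentative arrays), and biological order and slide column were not told apart. The same-number correlations were weak but all positive, so they do not settle whether the numbers pair the cultures. Same-numbered arrays also share a slide column. With the replicate block 2123 genes changed, 799 at least 2-fold, and 10 lists were called, of which 1, arginine, glutamate and proline biosynthesis (adjusted p = 0.0439), was not called without it.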

Other observations

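The test of gene families, the neighbour test and the replicon test below were chosen after the values were seen. Among 56 gene families that share the first 3 letters of a symbol and lie outside the gene lists, the hem genes of heme and porphyrin synthesis were the only family called. Of 14 measured, 11 rose and 2 fell in fermentative cells, with a median log2 fold change of 1.65 (camera adjusted p = 0.0178, and adjusted p = 0.657 with an estimated correlation). Over the 6 scaling and background alternatives the median lay between 0.96 and 1.65 and the adjusted p between 0.000227 and 0.0401.

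Several runs of adjacent locus tags changed at least 2-fold in a single direction, chosen here after their values were seen. The longest was SO_3175 to SO_3188, 14 genes that include wzy and rfbA, which fell with a median log2 fold change of -1.81 (-1.83 to -1.52 over the 6 scaling and background alternatives). The run SO_4448 to SO_4452, with modA of molybdate transport and moaA, moaC, moaD and moaE of molybdenum cofactor synthesis, rose with a median of 1.16 (0.69 to 1.16). On the megaplasmid (SO_A tags), which is not the plasmid with glk and galP, 5 genes from SO_A0047 to SO_A0051 fell. Their median was -2.59 (-2.62 to -2.08).

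The hypothesis that neighbouring genes changed together was tested over 4200 pairs of adjacent locus tags. Fold changes of neighbours had a Pearson correlation of 0.50 across these pairs, which are not independent replicates. Of 10000 shuffled gene orders the highest gave 0.06, a one-sided permutation p of 0.0001, the smallest these shuffles can give. Joint transcription of adjacent genes may account for this, but strand and operon limits were not used here.

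The hypothesis that genes on the megaplasmid (SO_A tags) fell more often than chromosomal genes did not hold. Of called megaplasmid genes 42.1% fell (32 fallen, 44 risen), against 47.2% of called chromosomal genes (964 fallen, 1080 risen), with a two-sided Fisher's exact p of 0.414.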
